A study of Mus musculus with 14 samples.

How the data were processed

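RNA was measured by sequencing in retinae of mice that carry a tamoxifen-inducible Cre recombinase under the Aldh1l1 promoter together with the NuTRAP allele, which tags ribosomes and nuclei of the recombined cells. Per the labels' protocols, 2 retinae were pooled per sample, part of the cleared homogenate was kept as input, and ribosome-bound RNA was then pulled down with an antibody against GFP (translating ribosome affinity purification, TRAP, called the positive fraction in the labels). The labels list 14 samples from old mice of 24 months (animals 214, 215, 521 and 523) and young mice of 4 months (animals 1382, 1383 and 1386), each with both fractions. Values were used for 13 libraries, because the table of the input fraction was matched to 3 old and 3 young animals. The input library of old animal 521 was not analysed here. In that table, 1 column names an animal that no label lists, and it was not used.

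The authors deposited 1 table per fraction, with normalized values on a log2 scale set against a baseline for each gene. Per the file headers, genes were kept where 100 percent of the samples of at least 1 of 2 conditions had a raw value of 5 or more, and genes follow RefSeq models. DESeq and the mm10 build are named in the submitters' processing notes, with no role given. The aligner, the counting tool and the log base are not given in the sources used here. There are 14732 genes in the table of the input fraction, 14832 genes in that of TRAP, and 14384 genes in both. Gene positions are those of the input table. Sequencing depth is unknown, because the deposited log2 values give no totals, so no interval based on counts is given. Values of some genes with few reads differ between libraries by the logarithm of ratios of small whole numbers. In the input table, 18 genes shared 1 difference between the first 2 libraries, 19 lay at that difference plus or minus 1, and 1 lay at it plus or minus the natural logarithm of 2, so the base was taken as 2. Whole-number multiples in every library (tolerance 0.02) were found for 3.43% of the input genes and 2.68% of the TRAP genes, too few for a test on counts. The base, the baseline and the scaling are thus read from the values and not stated by a source.

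The baseline bears on what a level means. In the input table, 64.5% of genes had 2 values of equal size and opposite sign (tolerance 2e-06), as centring on a median gives. The share was 0.0337% in the TRAP table, where 24.0% of genes were above 0 in all libraries. Among 203 genes with whole multiples in both tables, 44 had 1 and the same difference of baselines between the tables (tolerance 0.0005), and 22 more lay at that difference plus or minus 1. Leaving out differences that are a ratio of 2 away, the next most frequent was shared by 4 genes. This points to 1 baseline for both tables but does not show that the libraries of both were scaled together. The design written before the data were examined allowed a test between TRAP and input only for raw counts in both tables, and otherwise levels. The deposited values are not counts, so the comparison of the fractions is given as levels. A limma test across the tables was added after the data were seen, and every count from it is named as such.

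Age was tested within each table with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend, Benjamini-Hochberg adjustment, two-sided, threshold 0.05) on the values as deposited. The difference of the age effects between fractions was tested in limma with the means of the 4 groups on the genes in both tables. In this contrast a constant that differs between the tables cancels. All adjusted p-values are from limma or, for gene lists, from its camera function at a preset correlation of 0.01 between genes. Where fry or an estimated correlation is named, the adjusted p-value is from that test. Lists were also tested with a correlation estimated from the data and with fry. The 38 lists of cell type markers and pathways were fixed before the data were examined, and lists with fewer than 3 measured genes were not tested. None of the mitochondrially encoded list was measured. Some lists share genes, so counts of lists are not counts of independent results. Among others, the Müller glia list shares Slc1a3, Glul, Kcnj10 and Aqp4 with glutamate, potassium and water handling. The microglia list shares C1qa, C1qb and C1qc with complement. Each mouse gave 1 sample per fraction, so in the age tests within a table the p-values measure the spread between mice. The main fits across both fractions took the libraries of a mouse as independent. Their p-values ignore the pairing and do not measure that spread alone, and a fit with the animal as a block is given beside them.

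The rule for named genes was fixed before the data were examined. It took up to 12 genes per direction with the largest fold change among those at an adjusted p under 0.05, with a symbol that is not a predicted gene, a mean above the median gene, and groups that do not overlap. Up to 4 passing members per list and genes fixed in advance (Gfap, Vim, Aldh1l1, Rlbp1, Glul, Aqp4, Apoe and Kcnj10) were added. A further gene fixed in advance is not reported here. Because values are set against a baseline, the condition on the mean is not a filter on abundance. It favours genes enriched by the pull-down in the TRAP table, is close to arbitrary in the input table, and leaves no depleted gene in the comparison of fractions, where the rule used the added test.

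Both fractions of an animal are paired by the animal number in the labels. After removing age group means, the same animal's deviations in TRAP and input had correlations of 0.0613 to 0.208 across genes, and each of the 6 animals matched its own input best. No 2 libraries of a group were copies, since the smallest SD of the difference of 2 libraries over genes was 0.369. Alternatives were a common median, quantile normalization, limma without trend, limma with robust estimation and array weights, genes above the median value, a threshold of 0.10, a minimum fold of 1.5, each animal left out, and the animal as a block. A filter against none and a pseudocount were planned for other units and do not apply to log2 values. In simulated data with the spread of the TRAP values and 14832 genes, the age test recovered 44.8% of genes changed by 1 on the log2 scale, 77.6% of those changed by 2 and 83.3% of those changed by 3. For the interaction on 14384 genes the shares were 55.2%, 76.1% and 92.4%. Of all calls, 8 of 145 were false for the age test in TRAP and 12 of 161 for the interaction. The simulated noise was independent between genes, with 1 spread per gene over all libraries of a fit. In the real libraries many genes shift together, so these shares may not hold for them. Figures were drawn with matplotlib 3.10.9.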

Results

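Retinal RNA of old mice (24 months) was compared with that of young mice (4 months) in 2 fractions. TRAP is the ribosome-bound RNA pulled down from cells in which Aldh1l1-driven Cre was active, a promoter used to target astrocytes and Müller glia, the radial glia of the retina. Input is the whole-retina lysate set aside before the pull-down. There were 4 old and 3 young TRAP libraries, and 3 old and 3 young input libraries. Values are log2 levels relative to a baseline for each gene, and the sequencing depth is unknown.

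The first question was which cells the pull-down represented. Müller glia genes stood above the baseline in TRAP. In input they stood near it, but so do genes of any cell type. The input values are centred around the baseline, with 0% of genes above it in all input libraries and 0% below it in all. An input level near 0 thus says nothing about cell type. Rlbp1 (gene 19771, chromosome 7 from 79374870 to 79387027, mm10), the retinaldehyde-binding protein of Müller glia and pigment epithelium, had a mean level of 2.35 ± 0.78 in TRAP (SD, n = 7) and 0.01 ± 0.10 in input (SD, n = 6). Aldh1l1, whose promoter drives the Cre, stood at 2.74 ± 0.94 in TRAP, and the glutamine synthetase gene Glul at 2.09 ± 0.72. Apoe, Aqp4 and Kcnj10 had TRAP levels of 2.23 ± 0.77, 2.44 ± 0.62 and 2.36 ± 0.82. The tables of the fractions were deposited separately, so these are levels set across tables, and the planned design gives no test for them.

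Genes of the retinal pigment epithelium (RPE), the pigmented layer behind the photoreceptors, also had high TRAP levels. Rpe65, the isomerase of the visual cycle, stood at 3.95 ± 0.75, Ttr at 3.95 ± 0.73, Rdh5 at 3.93 ± 0.57, Rgr at 3.91 ± 0.56 and Kcnj13 at 4.09 ± 0.41 (SD, n = 7). The tight junction genes Cgn and Cgnl1 stood at 4.46 ± 0.53 and 4.27 ± 0.39. The astrocyte genes Gfap and Pax2 had levels of 2.56 ± 1.37 and 1.95 ± 0.64. Cone, amacrine, horizontal cell and rod genes stood below the baseline, while bipolar genes went both ways, with list medians of -0.63 to 0.65 over the TRAP libraries. The cone transducin gene Gnat2 stood at -2.38 ± 0.47, the amacrine genes Gad1 and Slc32a1 at -1.54 ± 0.40 and -1.63 ± 0.43, the horizontal cell gene Lhx1 at -1.89 ± 0.47, and the rod gene Nrl at -0.86 ± 0.47. In the limma test across tables, added after the data were seen, 4480 genes were higher and 4239 lower in TRAP among 14384, including all 18 Müller glia genes and 9 of 11 RPE genes higher, and 10 of 11 cone genes and all 9 amacrine genes lower. With quantile normalization the counts were 1485 and 1792, and at a minimum fold of 1.5 they were 2834 and 2000.

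One TRAP library stood apart. In young animal 1386 the median of the Müller glia list was 0.60, against 2.32 to 2.79 in the old TRAP libraries, and Rlbp1 stood at 0.64. The bipolar and rod list medians of this library were 0.65 and 0.06. Its X-inactivation transcript Xist stood at -6.27 in TRAP and -7.22 in input, and the Y-linked gene Ddx3y at 7.37 and 7.33. In the other libraries Xist was at -0.34 or above and Ddx3y at 0.40 or below. By these genes animal 1386 reads as male and the other animals as female. The young group thus holds the only male, and sex is partly mixed with age in the age comparisons.

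**Figure D1:**
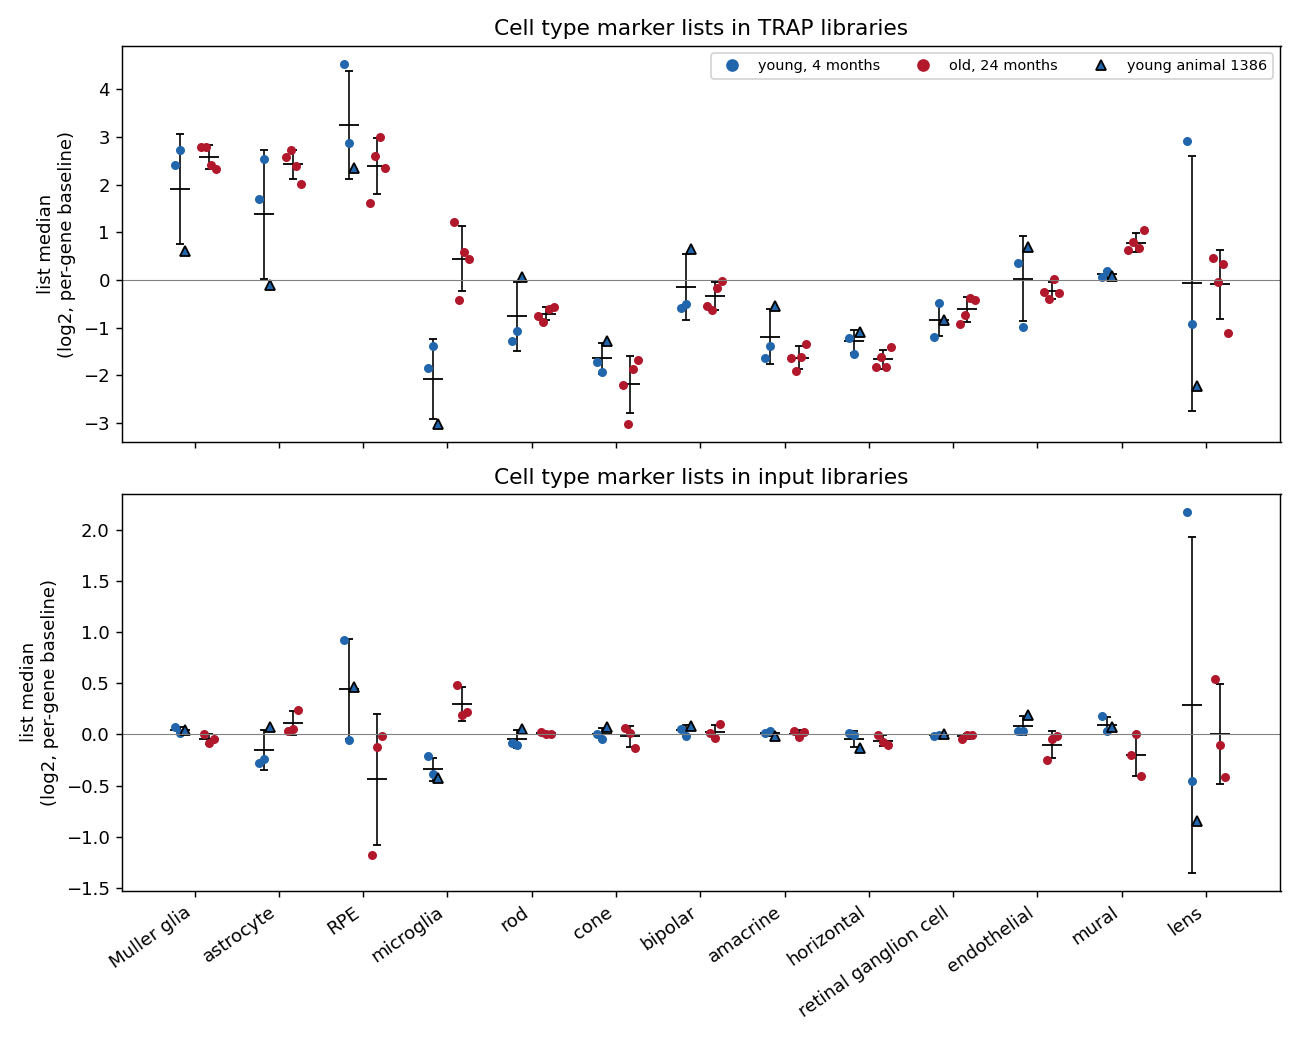
Each point is 1 library, and its height is the median log2 value, relative to the per-gene baseline, over the genes of a cell type list. Bars are the mean ± SD of young and old libraries, and the triangle is young animal 1386, whose Müller glia median of 0.60 in TRAP lies below those of the other TRAP libraries.

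The main question of the series was how the glial RNA differs between old and young retinae. In TRAP, Cxcl10, an interferon-induced chemokine, rose by 3.63 ± 0.49 on the log2 scale (SE, limma adjusted p = 0.0403), from 0.44 ± 0.76 in young (SD, n = 3) to 4.07 ± 0.43 in old mice (SD, n = 4). Ctss, the lysosomal protease cathepsin S, rose by 3.33 ± 0.37, and the class I histocompatibility gene H2-D1 by 1.18 ± 0.13. Other genes that rose were the gap junction gene Gjb6 (3.68 ± 0.45), the uridine phosphorylase Upp1 (3.50 ± 0.44), the tachykinin receptor Tacr2 (3.58 ± 0.38), the proteoglycan Dcn (2.84 ± 0.31) and the death receptor Fas (1.70 ± 0.25). Over the young TRAP libraries, Gjb6 had the same SD as P2ry13 (0.673309), and Tacr2 the same as Gpr34 (0.62141). Ratios of few reads give such repeats, so the sizes of the Gjb6 and Tacr2 rises are uncertain. The kainate receptor subunit Grik3, on chromosome 4 from 125490831 to 125714173 (mm10), rose by 2.54 ± 0.19 with a limma adjusted p of 0.0102. Heyl, Prtn3, Vgll3, BC030476 and Moxd1 rose by 1.75 to 2.44. In input, Prtn3 had the opposite direction, at -0.86 ± 1.00 in old and 0.58 ± 0.81 in young mice (SD, n = 3 each). The collagen gene Col3a1 fell by 2.36 on the log2 scale (limma adjusted p = 0.0263). Tmc4 fell by 1.40 on the log2 scale, and the Polycomb gene Cbx2 fell as well. Cxcl10, Gjb6, Tacr2 and Col3a1 had no values in input. Their age effects could not be set against input and were not part of the test between fractions.

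In all, 34 genes were higher and 11 lower in old TRAP at a limma adjusted p under 0.05 among 14832 tested, and 1889 had an unadjusted p under 0.05. The calls depended on single libraries. Leaving out animal 214 or 523 left 3 higher and 0 lower genes, leaving out 1382 left 8 and 0, leaving out 521 left 9 and 4, leaving out 215 left 19 and 2, and leaving out 1383 gave 69 and 80. Without animal 1386, 38 were higher and 8 lower, of which 21 and 1 were among the genes called with all libraries. Gjb6, Upp1, Ctss, Heyl, Prtn3, Moxd1, Fas, Tmc4 and Col3a1 then had limma adjusted p-values of 0.0504 to 0.0625, with log2 differences close to those with all libraries (Gjb6 3.49, Ctss 3.17, Col3a1 -2.42). In limma with array weights, which ran from 0.138 for animal 1386 to 3.82 for animal 1382, the counts were 1442 and 1323.

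Among the fixed lists, 1 of 15 class I histocompatibility genes passed over all genes, and all 15 passed when adjusted over the list alone. Of 15 microglia genes, Ctss passed over all genes and 14 when adjusted over the list alone. Trem2 and C1qb differed by 2.81 and 3.28 between old and young. Of 28 interferon response genes 0 passed in limma over all genes, 25 had an unadjusted p under 0.05, and 24 were higher and 1 lower when adjusted over the list alone. Of 17 reactive gliosis genes, those induced in stressed glia, Cxcl10 passed over all genes and 10 when adjusted over the list alone, while Gfap (gene 14580), the intermediate filament of astrocytes and stressed Müller glia, differed by 2.03 ± 0.65 with a limma adjusted p of 0.289 (1.29 without animal 1386). The median log2 differences of the class I, microglia, interferon response and reactive gliosis lists were 1.46, 2.51, 1.49 and 1.24. Camera called these lists higher in old mice, with adjusted p = 2.03e-12, 4.66e-14, 2.37e-12 and 3.3e-10. With an estimated correlation none passed, and their adjusted p-values were 0.527, 0.527, 0.702 and 0.528. Camera called 14 lists higher and 1 lower in all, the latter the amacrine list with a median of -0.48 (adjusted p = 0.00423, and 0.702 with an estimated correlation). Over all 34 lists tested, the lowest adjusted p with an estimated correlation was 0.527. With fry only the complement list passed (fry adjusted p = 0.0292). Its median was 1.25 (1.02 without animal 1386), with a camera adjusted p of 1.54e-06. The fry adjusted p-values of the class I, microglia, interferon response and reactive gliosis lists were 0.0513, 0.0513, 0.113 and 0.0513.

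Müller glia markers did not pass the test. Aldh1l1, Rlbp1, Glul, Apoe, Aqp4, Kcnj10 and Vim had differences of 0.99, 0.73, 0.58, 0.79, 0.55, 0.64 and 0.55, with limma adjusted p-values from 0.494 to 0.607. Without animal 1386, those of Kcnj10, Glul and Vim were -0.05, -0.04 and -0.11. Camera called the Müller glia list higher in old TRAP with all libraries (median 0.65, adjusted p = 0.00889, and 0.725 with an estimated correlation). Without that animal the median was -0.01 and the adjusted p 0.757. The Notch and progenitor list, which shares Hes1, Sox2, Sox9 and Lhx2 with the Müller glia list, likewise went from a median of 0.68 to 0.11. Without animal 1386 the amacrine median was -0.17 and the rod median 0.46, against 0.03 with it. The microglia, class I, interferon response and reactive gliosis medians without it were 2.25, 1.06, 0.93 and 1.21, and the NF-kB and cytokines median went from 0.63 to 0.26.

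**Figure D2:**
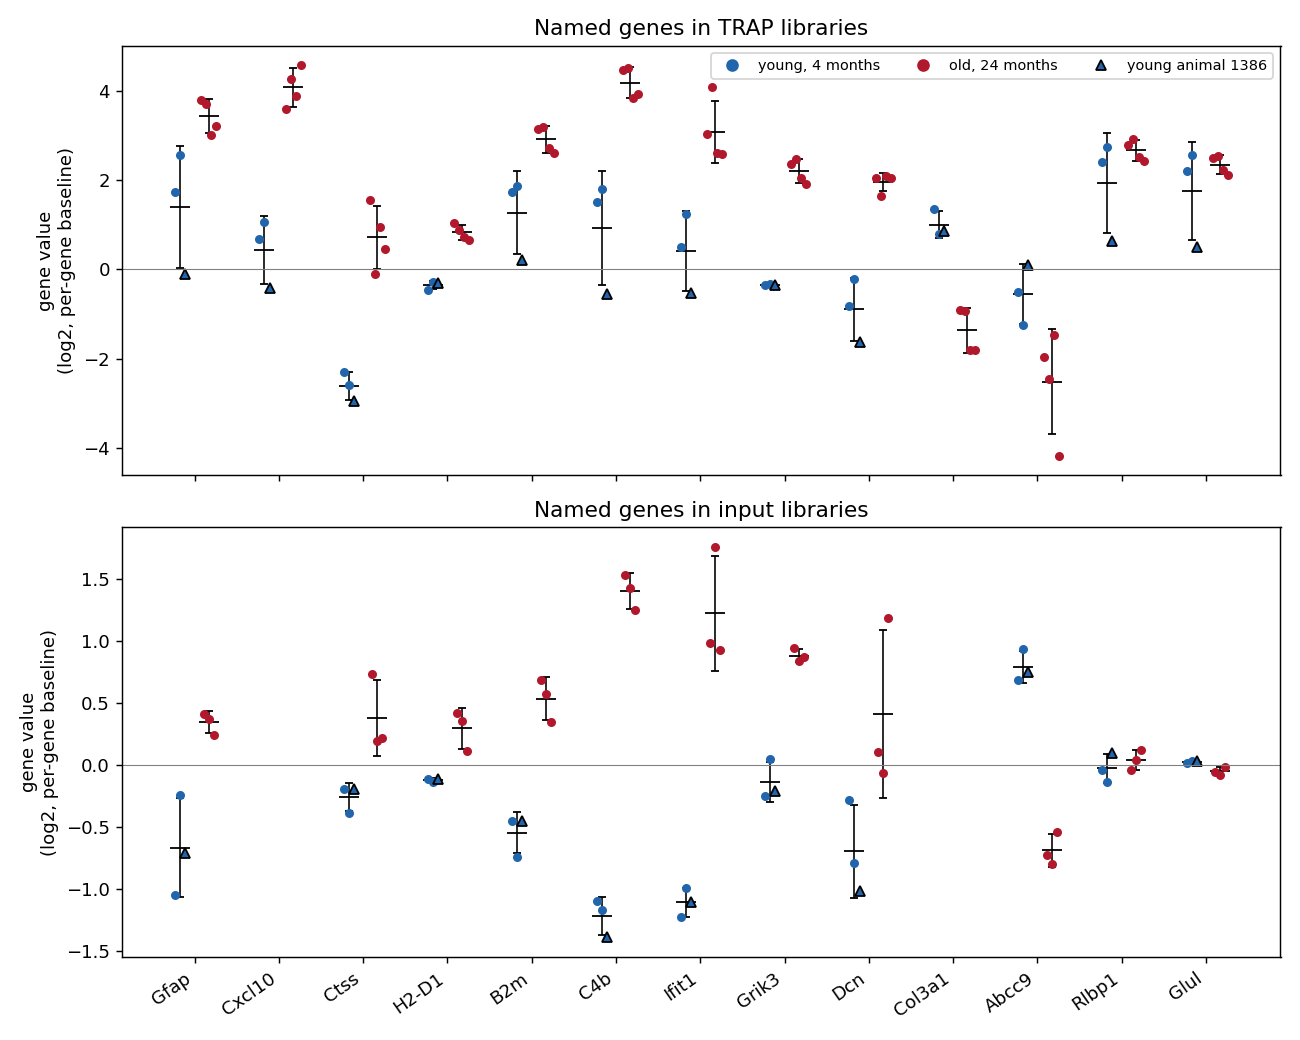
Each point is the log2 value of a gene in 1 library, relative to the per-gene baseline, with bars for the mean ± SD of young and old libraries and a triangle for young animal 1386. Cxcl10 and Ctss are higher in old than in young TRAP libraries, C4b is higher in old input, and the Müller glia genes Rlbp1 and Glul overlap between the ages in TRAP.

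The same comparison in input covered the whole retina. The complement gene C4b, on chromosome 17 from 34728381 to 34743897 (mm10), rose by 2.62 ± 0.11 on the log2 scale in old mice (SE, limma adjusted p = 0.00494), from -1.22 ± 0.15 in young to 1.40 ± 0.14 in old input (SD, n = 3 each). The interferon-induced genes Ifit1, Gbp6 and Ifi27l1 rose, Ifit1 by 2.33 ± 0.23 and Ifi27l1 by 1.80 ± 0.19, and the antiviral gene Zc3hav1 by 1.51 ± 0.14. In class I antigen presentation, H2-K1, B2m and the peptide transporter Tap1 rose by 0.87 ± 0.09, 1.08 ± 0.12 and 1.07 ± 0.12. Nod2, an intracellular receptor for bacterial peptidoglycan, rose by 2.42 ± 0.19, and Calcr, Csrp3, Tigd4, Calca, Rdh1 and Glb1l3 rose by 1.89 to 3.39. Aspn, Abcc9 and Sdc1 fell by 3.25, 1.48 and 1.36. Abcc9 is a potassium channel subunit of pericytes. C4b, Ifit1, B2m, Tap1 and H2-K1 were also higher in old TRAP, but none of them passed there over all genes. C4b stood at 0.92 ± 1.28 in young and 4.18 ± 0.35 in old TRAP, and Ifit1 at 0.41 ± 0.89 and 3.07 ± 0.70 (SD). B2m stood at 1.27 ± 0.92 and 2.91 ± 0.30. A call in input alone thus does not show a change confined to input.

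In input 41 genes were higher and 6 lower at a limma adjusted p under 0.05 among 14732 tested, and 1671 had an unadjusted p under 0.05. Leaving out any 1 of the 6 animals left 3 to 11 higher and 0 to 4 lower genes. With quantile normalization 23 were higher and 5 lower, and with array weights 82 and 26. Of 14 class I genes, 3 passed over all genes and 10 when adjusted over the list alone. Of 15 microglia genes 0 passed in limma over all genes, 10 had an unadjusted p under 0.05, and 10 passed when adjusted over the list alone, with a median of 0.83. Gfap differed by 1.01 ± 0.21 with a limma adjusted p of 0.152. Camera called 7 lists higher, namely class I, microglia, interferon response, reactive gliosis, complement, oxidative phosphorylation and erythroid genes, and 4 lower. The 3 erythroid genes, markers of blood, had a median of 0.76 (adjusted p = 0.028, and 0.411 with an estimated correlation). The lists called lower were RPE (median -0.98), visual cycle (-0.23), extracellular matrix (-0.25) and mural cells (-0.29). None passed with an estimated correlation, where the lowest adjusted p was 0.0698, for class I and for microglia, and RPE had an adjusted p of 0.465. The Müller glia list had a median of -0.07 and was not called (adjusted p = 0.0716). With fry, class I, microglia, complement and reactive gliosis were higher (fry adjusted p = 0.00584, 0.00584, 0.0086 and 0.0327). The mural list was lower (fry adjusted p = 0.00909).

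Age effects in TRAP and input had a correlation of 0.462 across the 14384 genes in both tables, where genes are not independent replicates. Over the 6 animals with both fractions it was 0.448, and the other ways of dividing these animals into 3 and 3 gave 0.134 to 0.272. Among genes in both tables, 6 were called higher with age in both fractions, against 0.0855 for independent calls, and 2 were called lower in both, against 0.00278. The fractions of an animal share its tissue, so these are not independent measurements. These genes were singled out after their values were seen. They were Agtr1a, Ces1a, Calcr, Nod2, Rnf43 and Ip6k3, higher by 1.42 to 4.00 in TRAP, and Prdm1 and Wnt7b, lower.

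Whether the age effect differed between fractions was tested directly. No gene passed at a limma adjusted p under 0.05, and the lowest adjusted p was 0.208. At an unadjusted p under 0.05 there were 758 genes, and 939 with the animal as a block, which also called 0 genes. Limma with array weights called 1158 genes with a larger and 1008 with a smaller age effect in TRAP, and quantile normalization 56 and 110. The genes with the smallest p were, in the direction of a larger age effect in TRAP, the microglial receptor genes Gpr34 (4.30 ± 0.69) and P2ry13 (2.76 ± 0.47), Ctss (2.69 ± 0.46), Tmem8c and Grik3, none of which passed. The young TRAP SDs of Gpr34 and P2ry13 repeated those of Tacr2 and Gjb6, as few reads give, so the sizes of their differences are uncertain. In the other direction Dnahc1, Snhg10, Rdh1, Ccr9 and Ppl did not pass either. Gfap had a difference of 1.03 ± 0.75. With quantile normalization the differences of Grik3 and Gfap were -0.71 and -0.57.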

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

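The tests of the 3 patterns weighed here were chosen after the values were seen, and the counts over other splits of the samples were planned before. Of 127 sets of libraries examined for a value far from the rest, 20 had one. Chance gives about 1 in 20 for independent sets, but these sets share libraries and genes, so the counts cannot be compared directly.

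Most far values were in the TRAP library of young animal 1386. Its list medians were -0.54 for amacrine cells, -0.11 for astrocytes, 0.35 for glutamate, potassium and water handling, 0.60 for Müller glia, 0.39 for Notch and progenitor genes, 0.65 for oligodendrocytes, -0.71 for ribosomal proteins and 0.54 for the visual cycle. Its values of Vim, Aldh1l1, Rlbp1, Glul, Aqp4, Apoe and Kcnj10 were 0.40, 0.71, 0.64, 0.50, 1.14, 0.52 and 0.61, each the lowest of 7. In young animal 1382 the TRAP medians of glycolysis and oxidative phosphorylation were -0.65 and -0.32. The oligodendrocyte median of old animal 214 in TRAP was -0.12, its Notch and progenitor median in input was 0.067, and the ribosomal protein median of old animal 523 in input was 0.15.

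For animal 1386, an exchange of its TRAP and input libraries, or fewer Müller glia in its retinae, are argued against by its input library, whose Müller glia median of 0.039 lies within the range of the other 5 input libraries (-0.08 to 0.07). Carry-over of whole-retina RNA in 1 proportion is argued against too: fitted on the Müller glia list, RNA enriched as in the other pull-downs would make up 8.56% and whole-retina RNA the rest, yet the RPE list (TRAP minus input of the same animal) lay 1.29 above the value this gives and the microglia list 2.55 below (-2.55), while the rod list lay close to it (0.066 above). It remains open whether fewer Müller glia were recombined, with other cells tagged in their place. The animal also differs from the others in Xist and Ddx3y, by which it reads as the only male. Whether sex bears on its low Müller glia values stays open as untested.

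For the higher microglia list in old TRAP, an increase of microglial RNA passed on alike to both fractions would leave TRAP minus input alike in old and young animals. It was 0.11 ± 0.68 in old and -1.73 ± 0.81 in young animals (SD, n = 3 each), a difference of 1.84. The exact permutation p was 0.1, the smallest that 3 against 3 animals can give, so this test cannot decide and the explanation stays open. Young animals 1382 and 1383 stood at -1.62 and -0.99, below the old ones (-0.61 to 0.72), and young animal 1386 at -2.59. More RNA of all untargeted cells in old pull-downs as the whole source is argued against by the amacrine list, which had a median age effect of -0.48 (the microglia list 2.51) and stood at -1.63 ± 0.24 in old TRAP, where the microglia list stood at 0.45 ± 0.67 (SD, n = 4 each). Without animal 1386 the medians were -0.17 for amacrine cells, -0.20 for cones, -0.30 for horizontal cells, 0.21 for retinal ganglion cells, 0.14 for bipolar cells and 0.46 for rods. The amacrine, bipolar and ganglion cell medians of old and young TRAP libraries then overlap. The rod medians do not, with -0.88 to -0.57 in old TRAP against -1.27 and -1.07 in young animals 1382 and 1383. A smaller change of this kind, or one in rods, thus stays open. The microglia median without animal 1386 was 2.25, which argues against the low library as its source. Microglial RNA held back selectively by the beads, recombination in microglia and glial expression of these genes remain open. Age itself was not separated from them.

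The RPE list differed between animals in both fractions. RPE carried along in different amounts at dissection is a candidate explanation: over the 6 animals the medians in TRAP and input had a Pearson r of 0.817 (exact permutation p = 0.0764) and a Spearman rho of 0.543 (exact permutation p = 0.297). Over the 4 animals nearest the median the r was -0.556, so the relation rests on 2 animals, and the data do not decide. With the age group means removed the r was 0.700. This relation was computed for 1 list, and an effect of age stays open, since the lower list in old input did not hold with an estimated correlation (adjusted p = 0.465 by camera).

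The age effect differed between fractions by camera at the preset correlation in 15 lists, none of which passed with an estimated correlation. The median differences (TRAP minus input) were -0.49 for amacrine cells, 0.33 for antioxidant and metal response, 1.03 for astrocytes, 0.64 for complement, 0.65 for glutamate, potassium and water handling, 0.37 for immediate early genes, 0.69 for interferon response, 0.57 for class I, 1.72 for microglia, 0.72 for Müller glia, 0.48 for NF-kB and cytokines, 0.67 for Notch and progenitor genes, 0.74 for reactive gliosis, 0.20 for retinal ganglion cells and 0.24 for ribosomal proteins. Without animal 1386, 5 lists were higher and 1 lower. The TRAP side of several medians rested on that animal. Without it the median age effect in TRAP went from 0.65 to -0.01 for Müller glia and from 0.68 to 0.11 for Notch and progenitor genes. It went from 0.31 to 0.03 for glutamate, potassium and water handling, and from 0.38 to 0.09 for antioxidant and metal response. For microglia it went from 2.51 to 2.25, and for reactive gliosis from 1.24 to 1.21.

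Other divisions of the samples were counted. For the 45 genes called with age in TRAP, 1 of 35 splits, the real one, gave as many, and the highest other gave 0. This met the share under 0.05 set in advance, but 1 of 35 is the smallest share these splits can give. Splits that mix old and young libraries also carry any age difference in their spread, which lowers their counts. Chance is thus made less likely for this count but is not excluded. For the 8719 genes of the added test between fractions, 1 of 100 drawn splits, the real one, gave as many and the highest other gave 1. These splits mixed TRAP and input libraries freely and ignored the pairing by animal. They cannot tell whether the tables were scaled alike, so no more is drawn from them. For the 47 genes called with age in input, 10 splits are too few for a share under 0.05, with 1 split as large and 1 gene in the highest other. For the interaction, 20 splits are too few, with 0 genes in the real split and 0 in the highest other. For the 15 lists called with age in TRAP, 14 of 35 splits gave as many and the highest other gave 18, so chance cannot be excluded for the number of lists at the preset correlation. For the 11 lists in input, 10 splits are too few, with 1 split as large and 6 lists in the highest other.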

How the results depend on the processing

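The Müller glia covariate, the test across tables and the estimated correlation without animal 1386 were chosen after the data were seen. The cause of the changes below was not tested unless stated.

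Genes higher and lower in old TRAP numbered 34 and 11. Lower genes were 4 with quantile normalization and 6 without trend. With array weights the counts were 1442 and 1323, with genes above the median 15 and 2 (fewer genes tested), at a threshold of 0.10 58 and 19, and with the Müller glia covariate 93 and 30. Leaving out 1 animal gave 3 to 69 and 0 to 80. In input (41 and 6) quantile normalization gave 23 higher, array weights 82 and 26, and a threshold of 0.10 gave 99 and 20. Leaving out 1 animal gave 3 to 11 and 0 to 4. Across tables (4480 and 4239) quantile normalization, which forces TRAP and input libraries to 1 distribution, gave 1485 and 1792, a minimum fold of 1.5 gave 2834 and 2000, and genes above the median gave 6 lower. Leaving out 1 animal gave 3961 to 4816 and 3754 to 4773. With the animal as a replicate block 4204 and 4029 were called. The interaction called 0 and 0, also with the replicate block, but 56 and 110 with quantile normalization and 1158 and 1008 with array weights. Leaving out 1 animal gave 0 and 0 to 2, the 2 without animal 1383.

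Lists called with age in TRAP (14 and 1) were 0 and 0 with an estimated correlation, with or without animal 1386, 1 and 0 with fry, 2 lower with the covariate, and 13 to 14 and 1 to 4 leaving out 1 animal. In input (7 and 4) they were 0 and 0 with an estimated correlation, 4 and 1 with fry, and 5 to 8 and 4 to 6 leaving out 1 animal. Across tables (12 and 7) they were 0 and 0 with an estimated correlation, 17 and 8 with fry, and 11 to 12 and 6 to 8 leaving out 1 animal. In the interaction (14 and 1) they were 0 and 0 both with an estimated correlation and with fry, 13 and 1 in the replicate block, and 5 to 14 and 1 to 2 leaving out 1 animal. The block changed no call by over 1.5 times. The mean Müller glia level in TRAP was 2.29, 2.25 with the block as the paired difference, and 2.21 to 2.58 leaving out 1 animal.

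Some genes that had not passed changed sign. The age effect in TRAP of Aqp4 was -0.083 with array weights, and with the covariate those of Kcnj10, Glul and Vim were -0.056, -0.029 and -0.11. Leaving out 1 animal gave -0.052 to 1.13 for Kcnj10, -0.042 to 0.99 for Glul and -0.11 to 0.95 for Vim in TRAP, and -0.51 to 0.069 for Aqp4 in input. In the interaction quantile normalization gave -0.71 for Grik3, -0.57 for Gfap and -0.075 for Apoe. Leaving out 1 animal gave -0.019 to 1.20 for Aqp4 and -0.037 to 1.12 for Rlbp1. Among the genes taken by the fixed rule, none that passed with all libraries changed sign under these alternatives, which were not run for the other genes called in both fractions. Filters against none and pseudocounts were not run, as they do not apply to log2 values. Depth is unknown, so what it limits could not be given beyond the repeated SDs of genes with few reads. The input library of old animal 523 had an SD over genes of 0.419, against 0.291 to 0.318 in the other input libraries. Its size factor relative to the first input library, read from whole-number multiples, was 0.527, against 0.968 to 1.10 in the others. That factor is ambiguous, so whether this library was less deep stays open.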

Other observations

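Without young animal 1386, an alternative planned for every animal, camera at the preset correlation called the rod list higher in old TRAP (median 0.46, adjusted p = 1.92e-08, and 0.61 with an estimated correlation), where with all libraries the median was 0.03. Only 2 young libraries remain in that comparison. All 14 rod genes were then positive. The cholesterol synthesis list had a median of -0.10 and the glycolysis list of 0.17. The lens list moved from 0.43 to -1.26, and lens medians of young animal 1382 were the highest in both fractions, 2.92 in TRAP and 2.17 in input.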
